A study of Caenorhabditis elegans with 2 samples.

How the data were processed

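The study measured chromatin immunoprecipitation with sequencing of GFP-tagged MEP-1 in whole L1 larvae of the strain OP102, with 2 biological replicates of 1 group and library fragments of 150 to 350 bp, per the labels. Sexes were pooled, per the labels. The aligner, the peak caller, their versions and the threshold of the irreproducible discovery rate (IDR) step are not given in the sources used here. A control was used in the authors' calling, per the deposited file lists, but no control library was analysed here.

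Each replicate has a relaxed peak list, both replicates pooled have another, and an optimal list was derived from these by the IDR step, per the deposited file lists. Column 7 of each list is the authors' signal value per peak, as deposited. Its scale differs between lists, so it was used only to rank or split peaks within a list. Column 9 holds the authors' −log10 q value as deposited, and it reaches a ceiling in each list. On ce11 the lists hold 4904 optimal, 30000 pooled, 30000 replicate 1 and 29149 replicate 2 peaks. The optimal list was checked to be exactly the 4904 highest-signal peaks of the pooled list. The lists give no read counts, so the depth of each library is unknown and no interval that needs it is given.

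Gene models were the 19973 protein-coding genes of Ensembl release 115 on the nuclear chromosomes I to V and X of WBcel235, and sequence came from the RefSeq assembly of the same build. Matched by symbol, 19531 genes were found in the RefSeq gene table and 17106 of them (87.6%) had the same start and end. Coordinates were not converted between builds, and the ce10 lists served as an alternative. For the ce10 tests chromosome lengths of ce11 were used.

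A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated 5' end of a protein-coding transcript. Summits outside windows were classed as exon, intron or intergenic. Chance was set by 1000 circular shifts of the summits within each chromosome with a fixed seed (two-sided permutation p, smallest 0.002; one-sided for replicate overlap, smallest 0.001). Peak shares by chromosome used exact Poisson and exact Clopper-Pearson binomial intervals at 95%. Gene lists were tested by two-sided Fisher's exact test over all protein-coding genes, adjusted by the Benjamini-Hochberg method over 27 lists and called at an adjusted p of 0.05. Odds ratios have 0.5 added to each cell. That addition, the bootstrap interval of rho (500 draws over peaks) and the percentile bounds for the mep-1 region were set after the data were seen. The names hsp-16.11 and hsp-16.49 of the heat shock list matched no gene symbol, while 2 of its other symbols each named 2 genes, so 18 genes were tested. Words of 6 bases were scored together with their reverse complements, within 50 bp of summits and of flanks 300 bp to each side, and 10 words were tested by Fisher's exact test on chromosomes not used to rank them. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for plots.

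The genes named in the text follow a rule set before the data were examined. They are the 15 genes with the highest-signal promoter peak, up to 3 members with and 2 without a peak in each list, 10 genes chosen for what is known of MEP-1, and the 5 strongest peaks outside promoter windows.

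The tests were tried on simulated data. With shifted summits and no effect, Fisher's exact test called a mean of 0.58 of the 27 lists per draw over 100 draws and 19973 genes. An adjusted p of 0.05 would give far fewer calls if genes were independent. The Fisher p-values are therefore too small and are to be read with the circular shifts. The shifts have a limit too, since shifted summits lay in promoter windows less often than the real ones. Circular shifts put 3.96% of lists past an unadjusted p of 0.05. Each shifted draw was ranked against the other draws of the same kind. A share close to this was therefore fixed in advance and does not test the shifts. Lists of 25 genes planted at an odds ratio of 6 were recovered in 87.5% of 200 draws and at an odds ratio of 3 in 36% of them. For lists of 10 genes the shares were 31.5% and 4.5%. Peaks in the planted lists were drawn for each gene on its own, so these shares leave out any dependence between genes. A word planted at 10% of shifted summits was recovered, and 0 words passed without it, in 1 draw each. Shifted summits were not matched to real ones in GC content, so this does not cover words that follow composition.

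Alternatives were a stricter peak threshold, each replicate alone, ce10 calls, other overlap rules, window sizes, gene backgrounds, flanks and word windows, and circular shifts for the lists. Restriction to outermost 5' ends and to genes in the middle 50% of chromosomes was added after the data were seen.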

Results

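Chromatin immunoprecipitation with sequencing was carried out on whole L1 larvae of Caenorhabditis elegans that carry GFP-tagged MEP-1, a zinc finger protein. The strain, OP102, carries an insertion targeting mep-1 in an unc-119 mutant background, per the labels. There were 2 biological replicates of 1 group, so no comparison between groups is implied, and the comparisons below set replicate against replicate and peaks against the annotated genome. The values are the authors' peak calls with a signal value per peak, and no control library was analysed here. The depth of each library is unknown because the lists hold no read counts. All coordinates are on ce11 (WBcel235), counted from 1.

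The optimal peak list held 4904 peaks. The strongest lay between genes on X at 11094011 to 11094411, with a signal of 919, and ranked 1 in both replicates. The next was upstream of the ribosomal protein gene rpl-3 (WBGene00004414) on III at 3867437 to 3867737, with a signal of 832. Signal over the list ran from 45.3 to 919 with a median of 82.5, and these are the authors' values, used only to rank peaks within a list. The peaks had a median width of 350 bp, from 88 to 1137 bp, and covered 1449 kb, which is 1.45% of the nuclear genome. The q value was at the ceiling of its scale for 2772 peaks (56.5%), so it does not rank those peaks.

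How far the replicates ranked the same places was asked first. The X peak at 11094011 was first in each replicate, and the peaks at Y17G9B.5 and cdc-48.1 were ranked 3 and 4 in both. The rpl-3 peak ranked 2 in replicate 1 and 6 in replicate 2. Lower in the list the ranks spread, as at mep-1, where the promoter peak ranked 2541 in replicate 1 and 614 in replicate 2. The let-418 promoter peak ranked 3916 in replicate 2 and had no overlapping call in replicate 1. Of the 4904 highest-signal peaks of replicate 1, 3828 overlapped one of the 4904 highest of replicate 2 (78.1%, exact 95% interval 76.9 to 79.2). Circular shifts of one list within chromosomes gave a mean of 3.14% and a maximum of 3.92% (one-sided permutation p 0.001, the smallest that 1000 shifts can give). Across the 4861 optimal peaks matched in both replicate lists, Spearman's rho of signal was 0.754 (bootstrap interval over peaks 0.738 to 0.767), and peaks are not independent replicates. With a match defined as a reciprocal overlap of 50%, rho was 0.677. Of the optimal peaks, 3769 (76.9%) were among the 4904 highest of both replicates and 50 of neither. Split into 10 groups by signal, the share found among the top peaks of both replicates was 99.8% in the highest group and 14.9% in the lowest. The list and the replicates were cut at the same number, so the lowest groups lie at the cut and part of this fall is set by it. An overlapping call of any rank in both replicates was found for 4861 optimal peaks (99.1%). The optimal list was derived from these same replicates, whose relaxed lists covered 9.99% and 9.29% of the nuclear genome. A high share is therefore built in, and rho describes only peaks selected from these replicates.

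**Figure D1:**
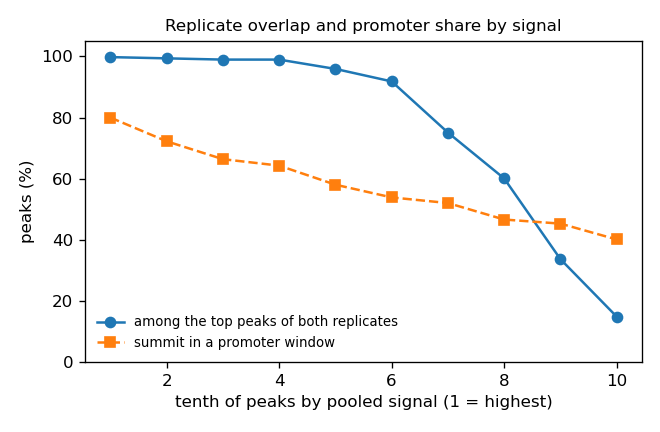
Share of optimal peaks (%, y axis) in each of 10 groups by pooled signal (x axis, 1 highest) that were among the 4904 top peaks of both replicates (circles) or had a summit in a promoter window (squares). The first falls from 99.8% to 14.9%, partly because the lowest groups lie at the cut, and the second from 80.0% to 40.1%.

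Where the peaks lie relative to genes was the next question. The summits at rpl-3, cdc-48.1 and rps-1 lay 270, 166 and 264 bp from an annotated 5' end. Of 4904 summits, 2839 (57.9%) lay in a promoter window of protein-coding genes, 1000 bp upstream to 200 bp downstream of a 5' end. Shifted summits gave 25.9% (2.24-fold, two-sided permutation p 0.002, the smallest possible). Introns held 14.5% of summits against 27.7% shifted (p 0.002), and exons held 1.73% against 21.8% (p 0.002). The intergenic share of 25.9% was not told apart from the shifted 24.6% (p 0.0839), and its direction changed with the window and the peak threshold. With a window of 500 bp it was 32.7%, above the shifted 29.4% (p 0.002), and with one of 2000 bp it was 16.6%, below the shifted 18.2% (p 0.016). The 24542 lower-ranked pooled peaks that overlapped no optimal peak had 30.2% of summits in promoter windows against 25.9% shifted, and 11.8% in exons against 21.7%. Within the optimal list the promoter share fell with signal, from 80.0% in the highest of the 10 groups to 40.1% in the lowest.

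Summits sat mainly upstream of the nearest 5' end. At rpl-12 the summit was 30 bp upstream of the 5' end, at lin-35 194 bp and at nspc-17 738 bp, while at atp-1 it was 2 bp downstream. The median signed distance was -208 bp, and 76.8% of summits were upstream. Within 200 bp of a 5' end lay 30.5% of summits against 9.90% of shifted ones (3.08-fold, permutation p 0.002).

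The chromosomes differed in peak density. III carried 62.6 peaks per Mb (exact Poisson 95% interval 58.5 to 66.9) and I carried 60.6 (56.7 to 64.6). II had 49.0, X 50.8 and IV 42.9 peaks per Mb, and V had the lowest density at 34.8 (32.4 to 37.5). X held 901 peaks, 18.4% of the list (exact interval 17.3 to 19.5), against 17.7% of the length (exact binomial p 0.197), and among the higher-signal 50% of peaks its share was 16.8%. The middle 50% of each chromosome held 3038 summits (61.9%, exact binomial p against 50% of the length 2.34e-63). It also held 11042 of the 19973 protein-coding genes, and the test was not adjusted for gene number. Of those genes 19.9% had a promoter peak, against 17.5% of all. These tests treat peaks as independent.

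The promoter share on X was not told apart from what its fewer windows give. It was 45.7% on X (exact interval 42.4 to 49.0) against 21.8% of shifted summits, and 60.6% on autosomes, from 56.4% on IV to 63.2% on V, against 26.8% (two-sided permutation p of the X to autosome ratio 0.298). The 5 highest-signal peaks outside promoter windows were all on X. They lay at 11094011 to 11094411, 3988 bp from the 5' end of W02H3.3, and at 13700657 to 13701042, nearest K02D3.1 (signal 746). The others were at 4209102 to 4209440 near F20B6.9 (676), at 9465705 to 9466040 near ZK899.6 (662) and at 8036241 to 8036783 near xol-1 (620). Of the 20 strongest peaks outside windows 12 were on X, against 1 of the 20 strongest inside windows. Over all 2065 peaks outside windows the X share was 23.7%, and inside windows it was 14.5%. Promoter windows covered 21.8% of the bases of X and from 24.4% to 30.3% of those of the autosomes.

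**Figure D2:**
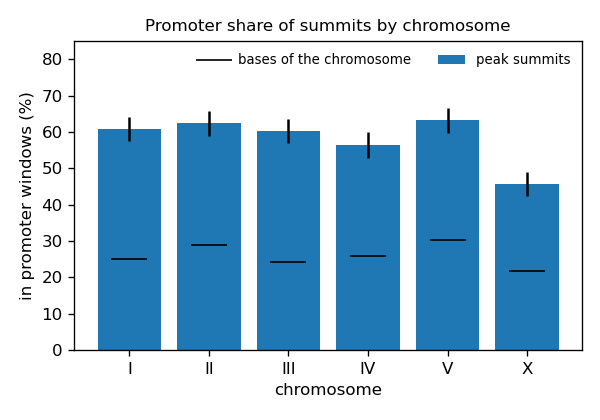
Share of optimal summits in promoter windows (%, y axis) on each chromosome (x axis), with exact 95% binomial intervals as error bars; the horizontal marks give the share of the chromosome's bases inside such windows. X is lowest at 45.7%, and the autosomes lie from 56.4% to 63.2%. The marks are also lowest on X, and how far this accounts for the difference was not settled.

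A promoter peak was found at 3495 of 19973 protein-coding genes (17.5%). The 15 genes with the highest-signal peak, each taken as the gene with the nearest 5' end, were led by rpl-3, Y17G9B.5 (WBGene00021202, signal 800), ekl-4 (WBGene00013676, 797) and cdc-48.1 (WBGene00007352, 795). The Y17G9B.5 peak at IV 4749921 to 4750243 also lay in the window of rpl-20, and the ekl-4 peak at I 14469174 to 14469490 in that of rps-20. Next came nspc-17 on X (713), rps-1 (645), eelo-2 (630), ska-3 (623) and egg-5 (613). The list was completed by cox-5A (575), rpl-15 (563), hsr-9 (555), eif-3.C (554), rpl-12 (549) and sec-61.G (536). The rpl-12 peak at IV 13240532 to 13240849 was also within the window of lin-54. Of the 2839 summits in windows, 850 (29.9%) lay in the windows of 2 or more genes, so a shared peak cannot be given to 1 gene. With the higher-signal 50% of peaks alone, 2270 genes had a promoter peak.

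A set of genes fixed beforehand for what is known of MEP-1 and of the strain was looked up whatever their values. The mep-1 promoter itself (WBGene00003218) had a peak at IV 11524347 to 11524505, with a signal of 107 and rank 1718. The promoter of let-418 had a weaker peak at V 5826246 to 5826595 (signal 56.3, rank 3888), and chd-3 had one at X 12852852 to 12853201 (63.8, rank 3355). The lin-35 promoter peak at I 5807406 to 5807621 was among the stronger ones (269, rank 269). No promoter peak was called at hda-1, unc-119, pgl-1, pgl-3, glh-1 or lag-2.

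Whether peaks gathered at particular kinds of gene was tested with 27 lists fixed before the data were examined. Members are named by the strongest peak in their window, and at rpl-20, rps-20, cox-6B, cdc-6, lin-54, lin-53, hsp-110, hsp-90, uba-2, col-38, mex-1, cosa-1, bli-6 and lin-7 that summit was nearer the 5' end of another gene. Ribosomal protein genes had the highest share, with a promoter peak at 67 of 79 (84.8%, odds ratio 25.9, Fisher's exact test adjusted p 8.39e-38), with the strongest peaks in the windows of rpl-3, rpl-20 and rps-20 and none at rla-1 or rla-2. Mitochondrial respiratory chain genes had one at 20 of 28 (odds ratio 11.4, adjusted p 3.41e-09), led by cox-5A, cox-6B (signal 471) and atp-1 (382), with none at gas-1 or lpd-5. Cell cycle genes had one at 20 of 33 (odds ratio 7.19, adjusted p 1.70e-07), led by pcn-1 (419), cdc-6 (379) and mcm-4 (227), with none at air-1 or cdc-25.1. Chromatin genes of the synMuv class had one at 14 of 23 (odds ratio 7.22, adjusted p 1.58e-05), led by lin-54, through the rpl-12 peak, lin-53 (381) and lin-9 (341), with none at hda-1 or hpl-2. Genes of the NuRD and MEC complexes had one at 7 of 10 (odds ratio 10.1, adjusted p 0.000986), among them lin-53, dcp-66 (160) and lin-40 (145). This list shares mep-1, let-418, lin-53 and hda-1 with the synMuv list, and all of these but hda-1 had a promoter peak. The synMuv and NuRD results are therefore not independent. Heat shock genes had one at 10 of 18 (odds ratio 5.84, adjusted p 0.000885), led by hsp-110 (459), hsp-90 (357) and hsp-1 (281), with none at hsf-1 or hsp-12.1.

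Heterochronic genes (6 of 11, adjusted p 0.0145), SUMO pathway genes (5 of 9, adjusted p 0.0248) and body wall muscle genes (10 of 28, adjusted p 0.0404) were also past the threshold. The strongest peaks in these lists were at ain-1 (signal 263), lin-28 (189) and lin-14 (160), at uba-2 (168), smo-1 (160) and ubc-9 (83.3), and at unc-112 (229), act-2 (132) and act-4 (115). When circular shifts replaced Fisher's exact test, these 3 lists were no longer past the threshold (adjusted p 0.447, 0.103 and 0.447). A further background was only the 8469 genes with any pooled summit in their window. Against it the NuRD and MEC list (odds ratio 4.28, adjusted p 0.0862) and the heat shock list (3.33, adjusted p 0.0698) were not past the threshold. The body wall muscle odds ratio was 0.964. This background comes from the same peak calls. It keeps all 3495 genes with a promoter peak and drops only genes without one (41.3% with a peak, in place of 17.5%). Calls lost there are not an independent test. The ribosomal protein, mitochondrial, cell cycle and synMuv lists were called with more peaks under every alternative run, but the size of the difference changed. With each summit counted for the nearest 5' end alone, the odds ratio was 6.75 for ribosomal protein genes and 7.50 for mitochondrial genes. Against genes with any pooled summit it was 5.33 for mitochondrial genes and 3.45 for cell cycle genes.

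Fewer promoter peaks than other genes were found in 5 lists. Chemoreceptor genes had 8 of 1308 (0.612%, odds ratio 0.0284, adjusted p 2.61e-97), among them sri-5 (signal 360) and srh-16 (302). C-type lectin genes had 6 of 240 (odds ratio 0.129, adjusted p 2.61e-12), the strongest at clec-126 (121). F-box genes had 22 of 322 (odds ratio 0.349, adjusted p 1.64e-07), led by fbxb-85 (370), and neuropeptide genes had 4 of 102 (odds ratio 0.214, adjusted p 0.000211), led by nlp-4 (184). Cuticle collagen genes had 16 of 156 (odds ratio 0.551, adjusted p 0.0306), led by col-38 (385). The collagen and neuropeptide lists were not past the threshold with circular shifts (adjusted p 0.447 and 0.0785). The C-type lectin, F-box and collagen lists were not past it against genes with any pooled summit (adjusted p 0.0672, 0.531 and 0.531). Among genes in the middle 50% of chromosomes the F-box list (odds ratio 0.523, adjusted p 0.318) and the heat shock list (2.95, adjusted p 0.16) were not past it.

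Germline lists were not told apart from other genes. P granule and germline RNA regulators had a promoter peak at 2 of 27 (odds ratio 0.462, interval 0.126 to 1.69, adjusted p 0.307), at mex-1 (signal 269) and cgh-1 (246). Meiotic chromosome genes had one at 2 of 25, at pch-2 (100.1) and cosa-1 (47.4), and sperm genes at 1 of 20, spe-39 (159). Intestine genes had none at 20, such as act-5 and asp-1 (adjusted p 0.0653 by Fisher's exact test and 0.00771 by circular shifts). Panneuronal genes had one at 8 of 24 (adjusted p 0.0938), led by snb-1 (166), and were past the threshold under 4 of the alternatives. Histone genes had 16 of 72, led by his-37 (418), hypodermis genes 2 of 29 with bli-6 (226), and nuclear hormone receptor genes 46 of 269 with nhr-47 (265). The ceh homeobox genes had 6 of 63 with ceh-38 (330), Hox genes 1 of 6, lin-39 (76.2), and pharynx genes 1 of 8, peb-1 (45.6). Wnt pathway genes had 6 of 26 with mig-5 (413), and vulval EGF-Ras genes 4 of 20 with lin-7 (328). Wide intervals such as 0.211 to 7.82 for the Hox list leave large differences either way possible.

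**Figure D3:**
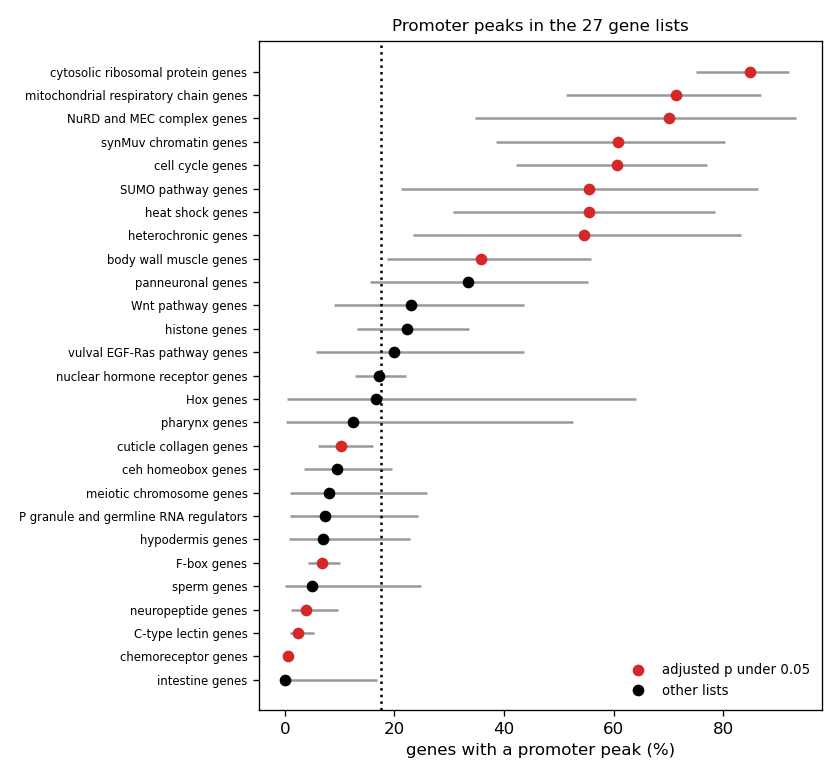
Share of genes with a promoter peak (%, x axis) in each of the 27 lists (y axis), with exact 95% binomial intervals; red points are lists past an adjusted p of 0.05 and the dotted line is the 17.5% of all protein-coding genes. Ribosomal protein genes are highest at 84.8%, and intestine genes lowest at 0%.

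Short non-coding genes were compared with shifted summits by class. A summit lay within 200 bp of 205 of 612 tRNA genes (33.5% against 2.31% shifted, adjusted permutation p 0.003), of 94 of 346 snoRNA genes (27.2% against 2.67%, adjusted p 0.003) and of 18 of 129 snRNA genes (5.76-fold over the shifted 2.42%, adjusted p 0.003). The piRNA genes were near a summit less often, at 67 of 15363 (0.436% against 1.79%, adjusted p 0.003). The miRNA genes (12 of 261, 4.60% against 2.44%, adjusted p 0.12) and rRNA genes (0 of 20) were not told apart from shifted summits. With a distance of 500 bp the miRNA share was 13.8% (adjusted p 0.0024).

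Which short sequences mark the summits was asked with 6-base words ranked on I, III and V and tested on II, IV and X. The word GACGCA lay within 50 bp of 15.2% of the 2399 test summits against 2.02% of flanks 300 bp away (odds ratio 8.63, Fisher's exact test adjusted p 2.93e-95). ACGCAG was at 15.6% against 2.38% (odds ratio 7.56) and CGTCTC at 17.1% against 3.06% (odds ratio 6.51). The GC-rich words ACGCGC and GAGCGC were at 9.59% and 9.55% of summits against 1.40% and 1.52% of flanks. All 10 words ranked highest on the discovery chromosomes passed on the others, the lowest being CGCGCG (odds ratio 4.42, adjusted p 3.53e-14). GC content was 44.6% at summits and 35.1% in flanks, and no test with flanks matched for composition was run. Fisher's exact test also treated each summit and its own flanks as independent, so their pairing was not used.

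Signal around mep-1 was compared with the rest of the genome because the labels name an insertion targeting this gene. Within 20 kb of mep-1 lay 19 pooled peaks against a median of 11 in 40 kb windows (percentile 84.2). The windows covered whole chromosomes and were not matched to the position of mep-1, which lies in the middle 50% of IV. With 10 kb each side the percentile was 93.1, and with 50 kb it was 95.1. The relaxed lists of replicates 1 and 2 held 18 and 15 peaks there (percentiles 82.5 and 73.3). The highest signal there was 377 (percentile 96.1), at a peak that is not the one at the mep-1 promoter. The 3 optimal peaks within 20 kb included the promoter peak at 11524347.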

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

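The outermost 5' end and the middle of chromosomes as settings were chosen after the data were seen. Settings identical to the main one are left out of the counts. For the main results 60 alternatives kept their direction and call, stayed within 1.5 times the main count or, for rho, stayed within its bootstrap interval, 4 went outside these limits and 1 reversed. With a reciprocal overlap of 50% rho was 0.677. With the higher-signal 50% of peaks 2270 genes had a promoter peak and X held 16.8% of peaks, below its share of the length (exact binomial p 0.266). Of 27 lists, 6 were called against genes with any pooled summit and 9 among genes in the middle 50% of chromosomes. These backgrounds test fewer genes, 8469 and 11042 in place of 19973. The first keeps all 3495 genes with a promoter peak. The number of lists hides exchanges, since circular shifts kept 9 of the 14 called lists and gained intestine genes, and the 500 bp window kept 10. The intestine gain was fixed by the lower promoter share of shifted summits and is no added evidence. Otherwise the cause was not tested.

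For single lists 268 alternatives kept the call or its absence, 28 lost a call, 8 gained one and 20 reversed. The 8 include the intestine gain by circular shifts, which was fixed in advance. For the ribosomal protein list the odds ratio ran from 6.75 with the nearest 5' end to 39.5 with the higher-signal 50%. The intergenic share was 19.8% with the higher-signal 50% and 16.6% with a 2000 bp window, below shifted summits in both. It was 32.7% with a 500 bp window and 26.1% without replicate 2, above them in both (p 0.002 and 0.044). With the higher-signal 50%, odds ratios were 0.866 for panneuronal, 0.60 for Hox and 0.599 for EGF-Ras genes. EGF-Ras genes gave 0.615 without replicate 1 and 1.69 without replicate 2, 0.984 against named genes and 0.957 in the middle of chromosomes. Pharynx genes gave 1.21 and nuclear hormone receptor genes 1.01 with a 500 bp window, and 1.30 and 1.32 with the nearest 5' end. A 2000 bp window gave 1.00 for nuclear hormone receptors. Hox genes gave 0.395 with outermost 5' ends and 0.985 against named genes. Against genes with any pooled summit, odds ratios were 1.02 for P granule, 1.42 for meiotic, 0.964 for body wall muscle, 1.42 for pharynx, 0.61 for Hox, 0.881 for Wnt and 0.512 for EGF-Ras genes. Of these lists only body wall muscle was called in the main test.

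Leaving out a replicate gave promoter shares of 57.7% to 59.2%, 3471 to 3594 genes, 14 to 15 lists and percentiles of 73.3 to 82.5 at mep-1. That percentile was 93.1 with 10 kb each side, 95.1 with 50 kb and 75.7 with optimal peaks alone. The share within 200 bp was 30.3% to 30.8%, that on X 18.5% to 18.7% and that in the middle 50% of chromosomes 61.8% to 62.1%. Non-coding classes numbered 4 to 5, and 10 words passed either way. The neuropeptide odds ratio was 0.256 without replicate 1 and 0.118 without replicate 2, and the chemoreceptor one was 0.0439 and 0.0287. Both of these lists kept their call. Other than at mep-1, the highest-signal pooled peaks are the optimal list itself, so that setting tests nothing. No paired analysis was possible because there is 1 group. The peak-interval setting used fewer shifts. Depth is unknown, so its limits could not be measured.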

Other observations

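The tests of crowded 5' ends, gene location, general transcription and the 2 parts of the X peaks, and all values on name prefixes, the longer word and tRNA summits, were chosen after the results were seen. The 12-base word was chosen after the places of the X peaks had been seen, though its matches had not been counted.

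Genes outside the fixed lists that share a name prefix were compared with all other protein-coding genes, those in the lists included. Named genes as a whole had a promoter peak more often (21.7%) than all genes (17.5%), and this was not adjusted for. Some prefixes stand for a mutant phenotype or a placeholder, such as unc (24 of 74) and tag (19 of 57), and are not gene families. Of 139 prefixes with at least 10 members, 17 had more and 10 had fewer promoter peaks than other genes (Fisher's exact test, adjusted over the prefixes). Integrator genes (ints) had a peak at 9 of 11 and eif translation factors at 18 of 25 (odds ratio 11.7, adjusted p 4.32e-07). Splicing genes (prp) and rbm genes had one at 9 of 13 each, npp nucleoporins at 16 of 26, rpn proteasome genes at 8 of 13, dnj chaperones at 16 of 29, and mrpl mitochondrial ribosomal genes at 20 of 41. None was found at 56 oac, 56 lgc, 56 irld or 31 msp genes (adjusted p 0.000502 for the first 3 and 0.0265 for msp). Circular shifts were not run for these prefixes. Fisher's exact test called lists too readily with shifted summits, so some of the prefix calls may be false.

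The overlapping words join to GAGACGCAG, which lay within 50 bp of 461 of 4904 summits (9.40%) and in 48 of 9808 flanks (0.489%). The word was put together from words ranked on I, III and V and from these same summits, so all its shares are a description and not a test. It was at 1.07% of the lower-ranked pooled summits. The share was 9.65% inside promoter windows and 9.06% outside. Only 1 of the 190 summits near tRNA genes had it, against 9.76% of the others. Of those 190 summits, 145 lay outside promoter windows.

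Of the 20 strongest peaks outside promoter windows 12 lay on X, and of the 100 strongest 32 did. Words of 31 bases that recur in the genome covered more than 50% of the summit region at 0 of the 32 X peaks and 0 of the 68 autosomal ones. Exactly repeated sequence thus did not fill these X summits. The comparison of X with autosomes had no contrast, and diverged repeats were not measured, so repeats of that kind stay open. A match of at least 10 of 12 bases to TCGCGCAGGGAG, a sequence tied to X dosage compensation, lay within 100 bp of 12 of the 32 X peaks (37.5%) and of 0 of the 68 autosomal ones (Fisher's exact test p 2.15e-07). At 500 bp from the same X summits 1 of 32 had a match. Among the 20 strongest, 9 of the 12 X peaks had one, including full matches of 12 at 11094011 and 2996903. Over all peaks outside windows a match was at 22 of 489 on X (4.50%) and 14 of 1576 on autosomes (0.888%). Inside windows it was at 2.67% on X and 0.659% on autosomes, so the excess on X is not particular to peaks outside windows. Whether these peaks lie at sites bound for dosage compensation was not tested, as no map of such sites was used here. The 5' ends of non-coding genes other than piRNA genes are argued against for the 12 X peaks among the 20 strongest, of which 1 lay in such a window (8.33%, exact 95% interval 0.211 to 38.5). They stay open for the other 20 X peaks, of which 13 did (65.0%, interval 40.8 to 84.6), against 16 of the other 60 autosomal ones (p 0.00309). Over the 100 strongest the shares were 43.8% on X and 26.5% on autosomes (p 0.109). The design has 1 group, so no comparison between groups tests a biological explanation.

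The 9 lists with more promoter peaks include ribosomal protein, mitochondrial and cell cycle genes. Crowded 5' ends are argued against as the whole cause, since 9 of the 9 lists were still called when each summit counted for the nearest 5' end alone. The odds ratios were lower there, at 6.75 in place of 25.9 for ribosomal protein genes and 7.50 in place of 11.4 for mitochondrial genes, so shared windows may carry part of the size. Location along the chromosomes was tested with circular shifts and among genes in the middle 50% of chromosomes. The shifts also move the peak-dense middle away from the genes there, so on central location only the second test bears. It is argued against for the ribosomal protein, mitochondrial, cell cycle and synMuv lists (adjusted p by shifts 0.0077 each) and the NuRD and MEC list (0.0337), which were past the threshold in both tests. In the middle their odds ratios were 26.6, 14.8, 6.60, 9.42 and 7.48, in the same order. Location stays open for the heat shock (0.036 by shifts), SUMO pathway (0.103), heterochronic and body wall muscle lists (0.447 each), which were not called in the middle (adjusted p 0.139 to 0.238). Their odds ratios there were 2.95 (95% interval 0.982 to 8.88) in place of 5.84 (2.36 to 14.4), 3.13 (0.774 to 12.7) in place of 5.77 (1.66 to 20.1), 4.02 (0.914 to 17.7) in place of 5.58 (1.79 to 17.4) and 2.54 (1.07 to 5.99) in place of 2.68 (1.26 to 5.72), in the same order. Each main odds ratio lay inside the interval from the middle. The middle held fewer of their genes (12 of 18, 7 of 9, 6 of 11 and 21 of 28), so the lost calls do not show that location is the cause. Signal at any open or heavily transcribed gene, whatever protein is precipitated, cannot be told apart from MEP-1 binding. A summit was near 33.5% of tRNA genes, and no precipitation of an unrelated protein is among the samples.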
